A study of Caenorhabditis elegans with 2 samples.

How the data were processed

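UNC-39 was measured by ChIP-seq in whole L4 larvae of 1 strain, with 2 samples that the labels call biological replicates 1 and 2. Both form a single group, so no conditions were compared. The deposited files are lists of regions in narrowPeak form, made on the genome builds ce10 and ce11. Per the labels and the notes deposited with the samples, each replicate's list was derived from that replicate's alignments and a further file. That file is taken here to be the control, because the notes also tie it to control-normalised tracks. The pooled list came from both alignments and the same file. The optimal list came from the pooled and both replicate lists by IDR (irreproducible discovery rate), a method based on how well ranks repeat between replicates. Not every optimal peak was strong in both replicates, and 2 had no region in replicate 2. The aligner, the peak caller, the IDR threshold, the read depth and the origin of the control are not given in the sources used here. The signal value of each region, used for all ranks, is the authors' own value from their peak caller, and its scale is not stated. The −log10 q of each region is likewise as deposited by the authors. Both describe and rank regions within a list. Between the replicates signal values were only correlated, and differences in amount between lists were not tested.

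The relaxed lists hold 30000 regions each on ce11, 400 bases wide in the pooled list and replicate 2 and 404 bases wide in replicate 1. They are made to hold background as well as peaks, and the pooled list covers 11.5% of the 100.3 Mb of the 6 nuclear chromosomes. The summit lies at the middle of each region. Because no read counts came with the lists, depth could not be stated, and weak regions cannot be told from noise by depth.

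Annotation and sequence were the worm assembly that ce11 corresponds to, with Ensembl genes, and lists on ce10 were never set against it. They served for counts, for overlaps and the correlation of replicates among themselves, and for matching optimal peaks between builds by chromosome and signal value. A region was assigned to the protein-coding gene with the nearest transcript 5′ end within 2000 bases of the summit, and short RNA genes were looked for within 500 bases. Shares were compared by Fisher's exact test, two-sided, between optimal peaks and the 29918 pooled regions that overlapped none of them. Adjusted p-values are Benjamini-Hochberg over the family named beside them, and intervals are exact Clopper-Pearson at 95%. Short sequences were searched on both strands within 100 bases of the summit, without mismatches except for the MEF3 site, where at most 1 was allowed. Overlap of the strongest regions was set against 1000 random draws. Matched background had 20 regions per peak of the same class of distance to a start and the nearest G+C content.

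The tests, 27 gene lists, 13 motifs and the alternatives were fixed before the data were examined, apart from those named as added later. Genes were named by a rule fixed then as well. It took the genes assigned to the 25 strongest optimal peaks, every list member at an optimal peak, up to 4 per list, and unc-39 and unc-119. Other genes named in the text fall outside that rule and serve to place a region or to give members of a list. The gene lists rest on gene names, on annotated gene types and on well known tissue markers. Alternatives left out each replicate in turn, changed distances, windows, backgrounds, overlap rules and the number of regions, and used ce10.

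The tests were run on simulated sets of 63 regions drawn from the pooled list. With nothing planted, 0 of 20 sets gave a call among 2080 words, and 1 of 20 sets gave a call among 27 gene lists. Such random sets lack the higher G+C content of the optimal peaks, so they cannot show how many word calls G+C content alone would give. For 6-base words planted in 30% of the regions, 184 of 200 (92.0%) were recovered, and 164 of 176 further calls were words that share 5 bases with a planted one. For gene lists with 5 planted regions, 25 of 25 were recovered, with 1 other call. Of the 27 lists, only these 25 had enough pooled regions to be tried. Fewer planted regions were not tried, so recovery of smaller excesses is unknown. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.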

Results

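The homeodomain protein UNC-39, a worm relative of vertebrate SIX4 and SIX5, was mapped on chromatin by ChIP-seq, in which DNA bound to a protein is pulled down with an antibody and sequenced. The material was whole Caenorhabditis elegans of the L4 stage, the last larval stage, with both sexes mixed. The strain, OP186, carries the transgene wgIs186, which makes UNC-39 with GFP and FLAG at its C terminus, in an unc-119 mutant background. There were 2 biological replicates and no other condition, so most comparisons set the strongest regions against weaker regions of the same experiment. Each replicate and the pool of both had a relaxed list of 30000 regions, and the optimal list, thresholded by IDR, had 63 peaks on ce11. Depth was not given with these lists and is unknown, and the intervals printed here cover counting error over regions only. Regions are not biological replicates, so a p-value here compares sets of regions and not larvae.

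The first question was where the optimal peaks lay. The strongest, with a signal value of 56.1, spanned X 13700596 to 13700995 between genes, and its nearest protein-coding start, that of K02D3.1, was 6111 bases away. Next came X 9465727 to 9466126 with 47.8 and III 9053868 to 9054267 with 44.7, the latter 278 bases upstream of R107.5. Of the 25 strongest peaks, 15 lay within 2000 bases of a protein-coding start. Among these were peaks upstream of egg-5, which acts in the egg-to-embryo transition (40.9), and of eat-16, a regulator of G protein signalling (37.2), and a peak in an intron of unc-108, the Rab2 GTPase (38.0). The peaks upstream of epn-1, the worm epsin (33.1), puf-9, a Pumilio-type RNA-binding protein (32.1), and spc-1, alpha spectrin (31.6), were all on X. A peak 144 bases upstream of F44E5.4, an Hsp70 family gene, had 35.1. The remaining genes of this set were F55G7.5 (41.9), tag-340 (40.4), F20B6.9 (36.6), col-94, a collagen gene (35.0), ZK1248.17 (33.8), F02E9.5 (32.5) and tos-1 (31.4). The peaks named for egg-5, col-94 and ZK1248.17 lay closer to the short RNA genes sls-2.4, R07E5.16 and sls-2.1.

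The optimal list was the head of the pooled list. All 63 optimal peaks were the 63 pooled regions with the highest signal values, which ran from 24.4 to 56.1 against a pooled median of 7.61. Membership thus followed the pooled signal value and did not require a high rank in each replicate. The second build gave 53 optimal peaks on ce10, again the 53 strongest pooled regions, and 52 of them had a partner on ce11 on the same chromosome with a signal value within 0.01. The 11 peaks on ce11 without a partner had ranks from 41 to 63. In all, 44 of the 63 peaks shared the highest −log10 q of the list, 1.94, so that value did not order them. One pair of peaks on III overlapped, at the snRNA gene R07E5.16, which leaves 62 distinct places.

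The replicates were compared to see how far each one carried the optimal list. The strongest peak, on X, ranked 2 in both replicates, and the peak at X 9465727 ranked 7 in replicate 1 and 9 in replicate 2. Other peaks were strong in a single replicate. The peak 59 bases from the start of tasp-1, the taspase gene, was the first of replicate 2 and ranked 5005 in replicate 1. That at tub-2, a Tubby-related gene, ranked 4 and 6094 in the same order. The opposite held for rpl-15, a ribosomal protein gene, with rank 18 in replicate 1 and 17781 in replicate 2, and the peak at klc-1, a kinesin light chain gene, ranked 5 in replicate 1 and had no region in replicate 2. These genes other than rpl-15 were picked after their ranks were seen.

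Of the 63 optimal peaks, 41 (65.1%, exact 95% interval 52.0 to 76.7) overlapped one of the 63 strongest regions of replicate 1, and 28 (44.4%, 31.9 to 57.5) one of replicate 2. Both conditions held for 15 peaks and neither for 9. The median rank of an optimal peak was 38 in replicate 1 and 117 in replicate 2. Among the 500 strongest regions of replicate 1, 69 (13.8%) overlapped the 500 strongest of replicate 2, against a mean of 2.996 and a maximum of 11 in 1000 random draws (one-sided permutation p = 0.001, the smallest these draws can give). The draws do not allow for overlap that a control shared by both lists would bring. Over the 9475 regions that overlapped between the full lists, log2 signal values had a Spearman correlation of 0.101 and a Pearson correlation of 0.169, across regions and with no test. In the 205 pairs among the 2000 strongest of each, Spearman rose to 0.30.

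**Figure D1:**
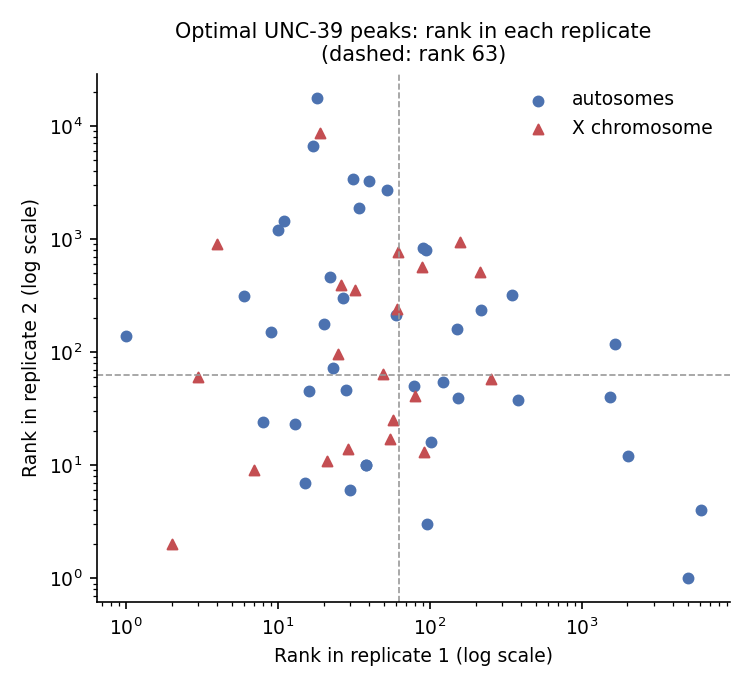
Rank of each optimal peak by signal value in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), for the 61 of 63 peaks with a region in both lists; dashed lines mark rank 63. Autosomal peaks are circles and X peaks triangles, and 15 peaks lie at or inside both lines.

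Optimal peaks lay mostly between genes. By the position of the summit, 39 of 63 (61.9%, exact interval 48.8 to 73.9) were intergenic, such as the peaks at egg-5, epn-1, spc-1 and tos-1, against 33.3% of 2000 other pooled regions drawn at random (Fisher's exact test, two-sided, adjusted p = 5.4e-05 over 10 classes). Only 2 peaks (3.17%), one in frpr-7 and one in dhc-4, fell in a coding exon, against 24.3% (adjusted p = 6.6e-05 by the same exact test). Introns held 15 peaks, among them those in unc-108 and in him-4, at 23.8% against 33.6% (adjusted exact p = 0.269). The nearest protein-coding start lay downstream of 46 of the 63 peaks, so that 73.0% (60.3 to 83.4) were upstream of it, against 45.8% of all other pooled regions (Fisher's exact test, two-sided, p = 1.9e-05). These 2 comparisons, of classes and of sides, were added after the data were seen. Sides were not compared within intergenic regions alone, so the excess of upstream peaks may restate that of intergenic ones.

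Closeness to a start was the comparison fixed in advance. Within 500 bases of a protein-coding start lay 19 of 63 optimal peaks (30.2%, exact interval 19.2 to 43.0), including those at R107.5, eat-16, F44E5.4, epn-1, puf-9 and tos-1. Of the other pooled regions 26% did, and Fisher's exact test found no difference (two-sided, p = 0.472). The direction turned when the 63 strongest regions of replicate 1 alone were used (23.8% against 26%, exact p = 0.775). The median distance was 888 bases for optimal peaks and 1206 for the other regions, and 44 peaks were assigned to 42 genes.

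The X chromosome held 21 of the 63 optimal peaks (33.3%, exact interval 22 to 46.3), among them the strongest 2 and those at epn-1, puf-9, spc-1 and ins-39. Of the other pooled regions 19.3% were on X, an odds ratio of 2.09 (Fisher's exact test, two-sided, p = 0.00952; adjusted p = 0.0286 over 6 chromosomes). Chromosome IV held 3 peaks, including rpl-15 and klc-1, 4.76% against 16.9% (adjusted exact p = 0.0286), and III held 15, including R107.5 and rpl-3, 23.8% against 14% (adjusted exact p = 0.0854). Only the test of X against the autosomes was fixed in advance. Those of the other chromosomes, and the adjustment over 6, were added later. Without either replicate the X share was 31.7% and 33.3%. It was 22.6% among the 500 strongest pooled regions, where the difference no longer passed (exact p = 0.0676).

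**Figure D2:**
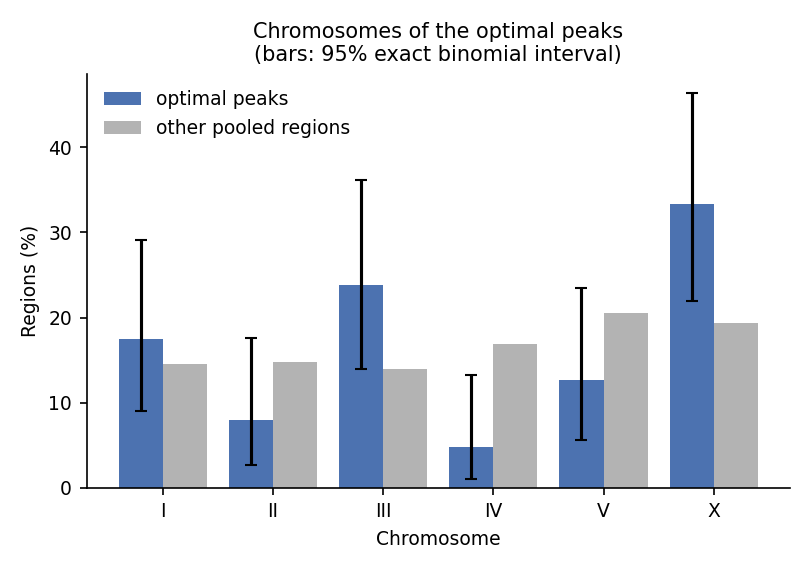
Share of the 63 optimal peaks (blue, with exact 95% binomial intervals) and of the 29918 other pooled regions (grey) on each chromosome, in percent. X has 33.3% of the peaks and 19.3% of the other regions, and IV has 4.76% and 16.9%.

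Whether optimal peaks hold the binding sequence of the SIX4 and SIX5 family was tested with TGAYAC, which covers both TGATAC and TGACAC. It stood within 100 bases of the summit in 14 of 63 optimal peaks (22.2%, exact interval 12.7 to 34.5) and in 14.4% of the other pooled regions, a difference that did not pass (Fisher's exact test, two-sided, p = 0.102). TGACAC stood in 11 peaks (17.5% against 8.04%, exact p = 0.0163, adjusted p = 0.106 over 13 motifs) and TGATAC in 3 (4.76% against 6.85%). The longer forms GGTATCA and TGACACC stood in 0 and 1 peaks, and the MEF3 site TCAGGTTTC, a different sequence searched with at most 1 mismatch, in 2. The share of TGAYAC was higher in the 31 strongest peaks (32.3%, exact p = 0.00921) and in the 63 strongest regions of replicate 1 alone (25.4%, exact p = 0.0184), and was 15.8% in the 500 strongest pooled regions (exact p = 0.368).

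Of the 13 motifs, GAGAGA alone passed the adjusted threshold. It stood in 27 of 63 peaks (42.9%, exact interval 30.5 to 56.0) and in 13% of the other regions (Fisher's exact test, adjusted p = 6.4e-08), and against regions matched on G+C content and distance class it kept a lead, with 21% (adjusted exact p = 0.00178). The homeodomain core TAATTA went the other way, in 1 peak (1.59%) against 8.61% (adjusted exact p = 0.135). Of the matched regions 3.89% had it (exact p = 0.511), so neither difference passed.

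Other short sequences set the optimal peaks apart. CGTCTC stood in 25 of 63 peaks (39.7%) against 6.70% of the other regions, and ACACAC likewise in 25 peaks against 7.96%. Among the further words were CACACA (41.3% against 10.1%), ACACGC (25.4% against 3.46%), ACGCAG (28.6% against 4.64%) and CGCGCA (23.8% against 3.06%). The A-rich words TGAAAA (23.8% against 54.7%) and ATCAAA (4.76% against 28.0%) were rarer in peaks. Of 2080 6-base words, counted with their reverse complements, 207 passed an adjusted p of 0.05 by Fisher's exact test, 159 of them more frequent and 48 less frequent in peaks. Optimal peaks were richer in G+C, with 46.6% ± 6.88 (SD over 63 peaks) against 36.4% ± 6.86, and against matched regions 29 words passed, all among the 207 and all more frequent in peaks, led by ACACAC, CACACA and CGTCTC. In the 63 strongest regions of replicate 1 alone 108 words passed, 87 of them shared with the 207, and in those of replicate 2 alone 212 passed, 114 of them shared.

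**Figure D3:**
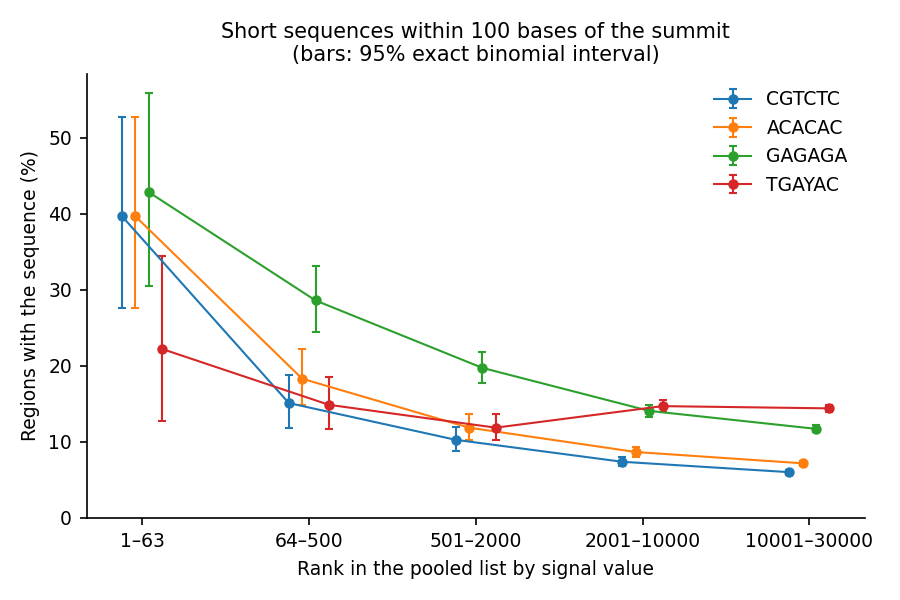
Percent of pooled regions with each sequence within 100 bases of the summit (vertical) by rank of signal value (horizontal, 5 classes), with exact 95% binomial intervals. CGTCTC goes from 39.7% at ranks 1 to 63 to 6.01% in the weakest class, while TGAYAC, at 22.2% in the peaks, shows no steady trend below them (14.9%, 11.9%, 14.7% and 14.4%).

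Among 27 gene lists fixed in advance, snRNA and spliced leader genes stood out. They lay within 500 bases of the summit in 5 of 63 optimal peaks (7.94%) against 42 of 29918 other regions (0.140%), an odds ratio of 61.3 (Fisher's exact test, two-sided, adjusted p = 1.3e-06 over the lists). The peaks were at sls-2.4 on I (signal value 40.9) and sls-2.1 on II (33.8), which encode SL2, the short RNA trans-spliced to downstream operon genes. The others were at R07E5.16 on III (35.0 and 26.9, overlapping) and sup-6 on II (29.3), both annotated as snRNA genes. The peaks at sls-2.4, sls-2.1 and R07E5.16 are the same ones that were assigned to the protein-coding genes egg-5, ZK1248.17 and col-94. The 32-base words of these 5 windows occurred only once in the genome for between 79.4% and 94.0% of words. Counting the overlapping pair once left 4 peaks (6.45%, adjusted exact p = 6.8e-05). In the 63 strongest regions of replicate 2 alone the list had 3 regions (4.76%), with an odds ratio of 34.7 (adjusted exact p = 0.0034).

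Ribosomal protein genes had 2 members among the 42 assigned genes, rpl-3 (30.8) and rpl-15 (26.3), 4.76% against 0.394% of other assigned genes (exact p = 0.0127, adjusted p = 0.172). The 63 strongest regions of replicate 1 alone had 3 members among 38 genes (adjusted exact p = 0.00662), and those of replicate 2 had 0 among 42 (exact p = 1), where rpl-3 ranked 1452. Histones had his-37, a histone H4 gene (29.7), neuropeptides had ins-39, an insulin-like peptide gene (30.4), and cuticle collagens had col-94, with adjusted exact p-values of 0.414, 1 and 1. Two-sided exact tests of snoRNA genes (F59C6.15 and M7.15) and of tRNA genes (2 peaks, near WBGene00014333, WBGene00014334 and WBGene00022939) gave adjusted p-values of 0.414 and 0.637. The remaining 18 of 22 protein-coding lists, muscle, mesoderm lineage, pan-neuronal and homeobox genes among them, had no member as the nearest gene of an optimal peak; F44E5.4 is not in the heat shock list, which rests on gene names. With 42 genes assigned, short lists had little chance of showing a member, so these zeros set no tight limit.

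The locus of the tagged gene itself held no region. Around unc-39 (V 14373074 to 14375881, WBGene00006775), none of the 30000 regions of the pooled list, replicate 1 or replicate 2 lay within 2000 bases. The stretch without regions ran from 14357333 to 14400291 in the pooled list, 43.0 kb, and was 42.7 kb in replicate 1 and 43.2 kb in replicate 2. The median stretch between pooled regions was 2114.5 bases. At unc-119 (III 10902641 to 10908935), the marker gene of the strain, the pooled list had 5 regions, the best at rank 1184 with a signal value of 13.9.

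**Figure D4:**
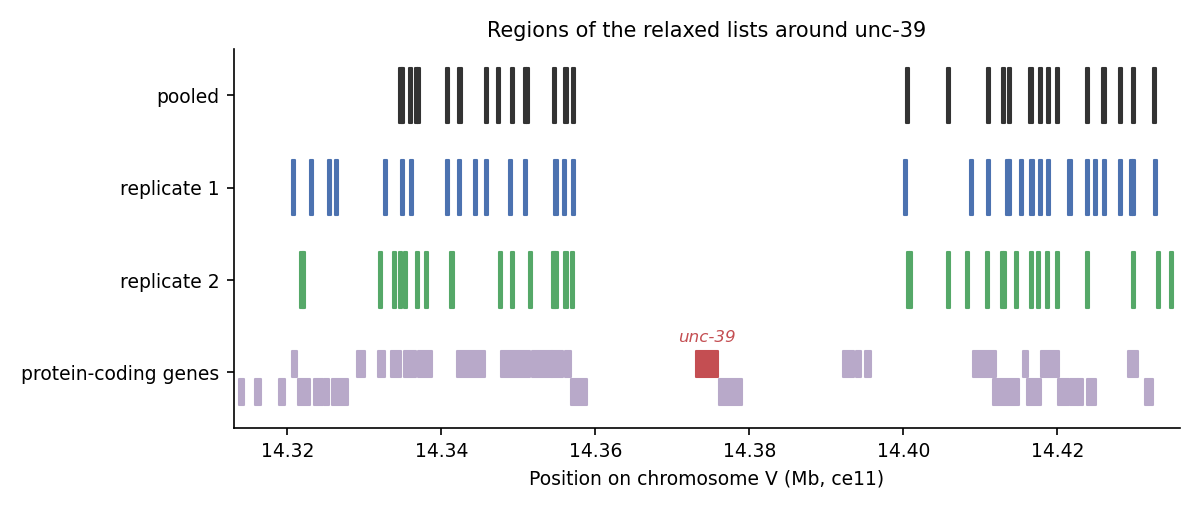
Map of chromosome V from 14313074 to 14435881 (horizontal, Mb on ce11) with regions of the pooled list, replicate 1 and replicate 2 as bars and protein-coding genes below, plus strand above minus strand. The window holds 29, 33 and 33 regions, and none of them lies in the 42.7 kb around unc-39.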

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

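Alternatives added after the data were seen were other strong regions (pooled ranks up to 2000) as background, peaks in the top 1000 of both replicates, overlapping peaks or regions counted once, and regions without CGCGCAGG. Differences between peaks and background are in percentage points, and causes were not tested unless said.

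For X the difference was 14 and stayed past the threshold in 6 alternatives. It was 3.31 for the 500 strongest regions. It was 7.03 without CGCGCAGG, but that word was picked from the peaks and all 6 peaks with it are on X, so the fall was fixed by the choice and says nothing on the X excess. Closeness to a start (4.16) did not pass anywhere. It was -0.196 for the stronger 31 peaks, -4.74 for peaks high in both replicates, and from -2.20 to 0.981 leaving out a replicate. TGAYAC (7.87) came to pass with the stronger 31 peaks (17.9), other strong regions (9.73), TGACAC alone (9.42) and without replicate 2. It ranged from 7.85 to 11.1 leaving out a replicate. These passes are by unadjusted exact p, and TGACAC did not pass after adjustment over 13 motifs (adjusted exact p = 0.106). TGAYAC did not pass within 50 bases (2.25), within 250 bases (7.90) or for peaks high in both replicates (6.92). Nor did it pass against matched background (9.13), against windows flanking the same peaks (7.14) or with the 500 strongest regions (1.44). TGATAC (-2.08), GGTATCA (-1.22), TGACACC (-0.528) and the MEF3 site TCAGGTTTC with at most 1 mismatch (-2.96) went the other way. The 207 words became 108 to 212 leaving out a replicate, 101 with the stronger 31 peaks, 485 with the 500 strongest regions, 29 with matched background, 61 with 50 bases and 71 against other strong regions. Drawing 1260 unmatched regions, as many as the matched ones, left 171 to 207 words in 20 draws, so the size of the matched background alone did not bring the fall. The 1 list became 1 to 2 leaving out a replicate (ribosomal proteins added without replicate 2), 6 with the 500 strongest regions, with overlapping regions counted once or not, and 2 with all genes within 2000 bases (histones added). That last setting takes every gene near a peak, so neighbouring histone genes at a single peak would count separately. The snRNA and spliced leader genes passed in the 9 that could change them (3 alter only protein-coding genes), with a share of 4.76% to 6.35% leaving out a replicate, against 7.94%.

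For the replicates, 88.9% and 65.1% of optimal peaks overlapped the 315 strongest regions of replicate 1 and replicate 2, and Spearman was 0.30 for the 2000 strongest. As −log10 q is tied at its maximum, 0 peaks lay above its median. Overlap of the strongest regions exceeded the random draws in all 4 alternatives, by 190.5-fold for the 100 strongest and 4.39-fold for the 2000 strongest, against 23.03-fold. With unknown depth, no limit on weaker sites can be given.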

Other observations

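Of the tests in this part, the counts of 10-base words and of CGCGCAGG, the tRNA comparison on X, overlapping regions counted once, words inside and outside short RNA genes, shares of genes in long stretches and other strong regions as background were chosen after the results were seen, as was the 5% bound for words kept after matching. A 10-base word, CCCTGCGCGA, stood in 6 of the 63 optimal peaks and in 4 of the 29918 other pooled regions. On the other strand it reads TCGCGCAGGG, which is most of the MEX motif, the sequence at which the worm dosage compensation complex is recruited to X. All 6 peaks with its part CGCGCAGG were on X, where they made up 28.6% of the 21 X peaks. They were the peak at X 11094020 to 11094419 (rank 4), those near F20B6.9 (rank 13), xol-1 (rank 18, 4857 bases from the start of this sex determination gene), ins-39 (rank 29), gtr-1 (rank 53) and nspc-17 (rank 58). Among the other regions 34 had it, 14 of them on X (6 of 63 against 34 of 29918, with no test, since the word was picked from the peaks). The most frequent 10-base word was GAGACGCAGA, in 10 peaks (15.9%) including those at R107.5 and F44E5.4, against 1.01% of the other regions.

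Among the 500 strongest pooled regions, pan-neuronal genes had 5 members of 326 assigned genes, unc-11 (signal value 22.8), rab-3 (22.8), syd-2 (22), unc-10 (17) and unc-44 (16.5), against 17 of 11653 other assigned genes (Fisher's exact test, adjusted p = 0.00157 over 27 lists). Mitochondrial respiration had cox-5B, atp-4, cox-5A, ucr-1 and nuo-4 (adjusted exact p = 0.00321). The pan-neuronal and mitochondrial regions had pooled ranks from 83 to 494, so none of them was an optimal peak. The tRNA genes had 14 regions at 12 distinct places, 8 of them on X (66.7%). Of the other 243 places near tRNA genes 42% were on X, and the difference did not pass (Fisher's exact test, two-sided, p = 0.134).

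No region lay at unc-39. Its stretch was longer than 27295 of the 27304 stretches between pooled regions (99.97%), so an ordinary gap is not what the lists show, although 14.1% of protein-coding genes had no region within 2000 bases and 0.611% lay in a stretch at least as long. In that stretch 94.7% of 32-base words occur once in the genome, so sequence that cannot be placed does not account for it. In both replicates the stretch was at least 42.7 kb, the size of a large genomic insert, although that of this transgene is not given in the sources used here. Extra copies of the locus from the transgene would raise the control as well only if the control came from this strain, and its origin is not given. In that case they may account for the stretch. A mask over the locus in the authors' processing would leave the same stretch and was not tested, nor was a biological explanation.

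Peaks at snRNA and spliced leader genes were the list that stood out, and reads shared between copies stay open for them, since a median of 81.6% of the 32-base words in their windows occur once, between the bounds set in advance. Of the words that touch the gene, 41.5% to 84.4% occur once, while all words in the rest of each window do. Signal at highly transcribed genes in general, for example from open chromatin and not from UNC-39 as such, could also bring them: among the 500 strongest pooled regions 3 of the 4 lists of ribosomal proteins, histones, tRNA genes and snoRNA genes passed an adjusted exact p of 0.05 (all but histones), also with overlapping regions counted once. Translation factors (0.307% against 0.335%), the proteasome (0 of 326) and cuticle collagens (0.613% against 0.884%) had no excess there (adjusted exact p = 1 for each). These lists were not among the 4 set in advance for this question. Mitochondrial respiration, also outside the 4, did pass there. The snRNA and spliced leader genes also stood above other strong regions (7.94% against 0.259%, adjusted exact p = 0.000163), but these have lower ranks, so a general rise with rank stays open too, as do expression and open chromatin.

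Short sequences over-represented in optimal peaks might follow from their G+C content. After matching on G+C content and on the class of distance to a start together, 14% of the 207 words stayed past the threshold, so G+C content is not the whole cause, while the part of each in the loss of the other words was not separated. Many of the words that stayed overlap one another, as AGACGC, GACGCA, ACGCAG and CGCAGA do within GAGACGCAGA. Their share therefore counts some sequences more than once. Against other strong regions 71 of the 207 words passed, but these have 38.8% G+C against 46.6% in the peaks, which may bring such calls. The share of ACACAC also grew with rank outside the optimal peaks, from 11.9% at ranks past 500 up to 2000 to 18.3% at ranks 64 to 500 and 39.7% in the peaks, and that of GAGAGA from 19.7% to 28.6% and 42.9%, while G+C content rose from 38.3% to 40.6% and 46.6%. No biological explanation was tested for these words.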
